A study of Mus musculus with 6 samples.

How the data were processed

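Total RNA was extracted with Trizol from fat of wild-type C57BL/6 mice and sequenced on an Illumina instrument, with 3 libraries before grafting and 3 libraries 7 days after grafting. The deposited values are a gene-level signal: the authors' gene read counts, divided by 1 size factor per library. This was read from the values, because 100% of them in every library were whole multiples of 1 step (within 0.01 reads), with steps of 0.96979 to 1.01304. The 6 deposited per-sample tables held the same values as the table of the whole series, and the authors' mean of each group, also a deposited signal, was not used. The deposited gene lengths, in base pairs (unit: other), were not used either. The submitters name Bowtie 0.12.2 and HISAT2 2.0.5 and the builds mm8 and mm9, but the deposited coordinates match GRCm38: of 12163 listed genes, 12151 were found in the GENCODE M21 annotation and 12029 lay within 1000 bp of it. The counter, the strand use, the normalization tool and the gene filter are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart.

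The table had been selected on the outcome. Its order followed the p computed here (Spearman correlation across genes 0.978, genes not being independent replicates), 10772 of 10854 tested genes had an unadjusted p under 0.05, and 51 lay within 0.25 of 0 on the log2 scale. The normalized totals, 12846005 to 15443409, therefore cover listed genes only, and the full depth is unknown. The Benjamini-Hochberg adjustment ran over all 55450 annotated genes, with unlisted genes entered at the highest possible p. The variance prior could be estimated only from the selected genes, which is a limit of every p given.

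A count model had been planned before the data were examined, and was replaced by a model of the normalized values as deposited. Log2(value + 1) was fitted with limma 3.58.1 in R 4.3.3 (moderated variances with a mean trend, robust), for genes with a value of at least 10 in at least 3 libraries, with group as the only term, two-sided, and an adjusted p under 0.05 as the threshold. Log2 fold changes are grafts over before grafting, with SE, and ± is the SD of 3 libraries. Tables were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. On simulated data with known changes in 100 genes at each size, 59% of changes of 1 and 93% of changes of 2 on the log2 scale were recovered, with 4 false calls among 10601 unchanged genes. Most simulated genes were unchanged, unlike those of the selected table, so these rates do not carry over to the calls reported here.

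Before the data were examined, 55 gene lists were fixed: adipocyte markers, lipid synthesis, fatty acid oxidation, citric acid cycle and respiratory chain, brown and beige fat, glycolysis, hypoxia, insulin and adrenergic signalling, 3 macrophage lists, cytokines, chemokines, neutrophils, T and NK cells, B and plasma cells, dendritic cells, complement, interferon, 3 matrix lists, progenitors, endothelium, proliferation, cell death, lysosome, antioxidants and the unfolded protein response. Lists of other tissues and checks covered skeletal muscle, epithelium, male tract, mesothelium, lymph node, red cells, Schwann cells, smooth muscle and pericytes, mast cells, platelets, lymphatic endothelium, immediate early genes, the circadian clock, sex-linked and housekeeping genes. Families by name were ribosomal proteins, mitochondrially encoded genes, mitochondrial ribosomal proteins, complex I, proteasome, vacuolar ATPase, collagens, histones, immunoglobulin variable segments, keratins and major urinary proteins. Camera compared each list of at least 5 tested members with the other genes, with a preset correlation of 0.01 and with an estimated one, adjusted over 46 lists. Those other genes had themselves been selected for a difference. With an estimated correlation the test has only the few residual degrees of freedom of 6 libraries, so it has little power to call a list. Fry, which tests whether a list's genes move one way on balance (40 called) or in either direction (45 called), compares no list with other genes. Without members shared between lists, camera called 31 of 45 with the preset correlation.

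Genes named were the 10 called higher and the 10 called lower with the largest change (mean of at least 10 CPM of the listed total in the higher group, groups separate, predicted names left out), up to 3 called members per list in its main direction and 2 in the other, and 26 genes fixed in advance. Of the latter, Cd163, Mrc1 and Pecam1 were outside the table and not analysed here. Some genes that the rule names are not reported here. Where a group had 0 reads, the fold is a bound taken at 3 reads in each library, and with 1 to 3 reads the ratio has an exact 95% binomial interval. Intervals and bounds cover counting error only. The titles' numbers were tested as pairs: correlations of same-numbered libraries, after removing group means, were -0.156, -0.126 and 0.047 across genes, so they were not paired. Rescalings, pseudocounts of 0.5 and 8, filters, precision weights, stricter thresholds, a replicate term and leaving out each library were tried as alternatives.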

Results

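Fat tissue of wild-type C57BL/6 mice, an inbred laboratory strain, was profiled by RNA sequencing before grafting (3 libraries) and 7 days after grafting (3 libraries), and the submitters describe the libraries of each group as biological replicates. The labels used here give no depot, graft site or sex. The deposited table lists 12163 genes, which took between 13027776 and 15924559 reads in each library. Its values are normalized read counts, that is, reads divided by 1 size factor per library, and all levels below are means ± SD of these values with n = 3 per group. The listed genes had been selected for a difference between the groups, so genes outside the table were not analysed here. A gene's absence may mean that it did not differ clearly or was removed by a filter that is not given. These cannot be told apart, so absence is not read as a result for any gene.

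The comparison asks how the transcriptome of fat differs 7 days after grafting from that of the tissue before it was grafted. All 20 adipocyte markers fell. Adipoq, the gene of the hormone adiponectin, went from 33177 ± 5056 to 380 ± 246 normalized counts, and Plin1, which coats the lipid droplet, from 20999 ± 2428 to 670 ± 736, or 245.9 without graft replicate 1. Il1b, which encodes interleukin 1 beta, went from 11.6 ± 4.0 to 22297 ± 8017, and the acute phase gene Saa3 from 7.6 ± 4.5 to 119264 ± 26257. Of 18 macrophage markers 16 rose, as did all 20 fibrillar collagen and matrix genes, all 13 tested glycolytic genes and all 20 proliferation genes. All 9 tested B and plasma cell markers fell, as did 11 of 13 tested T and NK cell markers. As sets, camera called 32 of the 46 lists tested with a preset correlation and 0 with an estimated correlation.

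**Figure D1:**
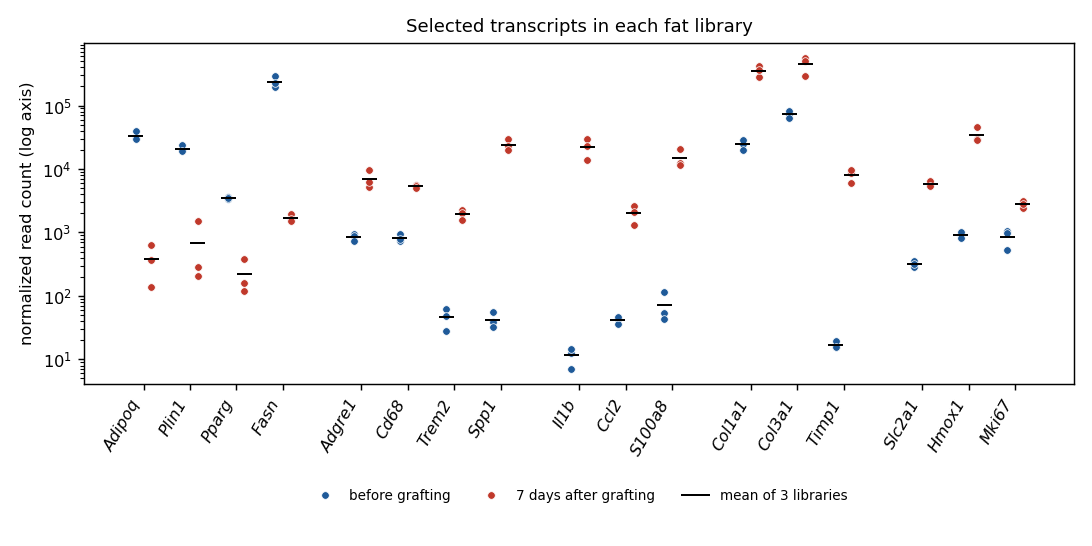
Normalized read counts (vertical log axis) of 17 transcripts in each of the 6 fat libraries, blue before grafting and red 7 days after grafting, with a black bar at the mean of 3 libraries. Adipoq, Plin1, Pparg and Fasn lie lower in all 3 grafts, and the other 13 transcripts lie higher in all 3 grafts.

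Among 10854 tested genes, limma called 4479 higher and 4251 lower in grafts at an adjusted p under 0.05, so that 51.3% of the 8730 calls were higher. Of these, 2782 were higher and 3022 lower by at least 1 on the log2 scale, and 681 were higher and 926 lower by at least 3. The values of all 3 libraries of a group lay above those of the other group for 97.6% of tested genes, against 10% by chance, in a table that had been selected for difference. The median log2 fold change of the tested genes was 0.28, and it moved to -0.48 when the ribosomal protein genes were set to no change, which left 1947 genes higher and 5714 lower (25.4% higher). The median was 0.17 after rescaling by median ratios, 0.15 with equal listed totals and 0.09 with equal upper quartiles, with 44.7%, 43.6% and 41.4% of the calls higher. Spearman correlations between libraries were 0.9851 to 0.9929 within groups and 0.7862 to 0.8195 between groups, and the first principal component held 90.6% of the variance.

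The called genes with the largest rises were Saa3, Acod1, Cxcl2, Arg1, Cxcl3, Fpr1, Cxcl5, Serpinb2, Clec4d and Il1b. Saa3 (chromosome 7, 46711998 to 46715700, minus strand, GRCm38) rose by a log2 fold change of 13.89 (SE 0.40, adjusted p = 1.14e-06). Arg1, the arginase of alternatively activated macrophages, went from 4.3 ± 0.5 to 38801 ± 10279, a log2 fold change of 12.80 (SE 0.21, adjusted p = 2.87e-07). Acod1, the enzyme that makes itaconate in activated macrophages, had 2 reads in all libraries before grafting and 16196 ± 5599 normalized counts in grafts, a ratio of 24670 with a 95% counting interval of 6790 to 202600. The neutrophil-attracting chemokines Cxcl2, Cxcl3 and Cxcl5 rose as well. Cxcl3 had 0 reads in every library before grafting and was at least 1967-fold higher in grafts, taking 3 reads in each library as the floor. Fpr1, a receptor for formylated bacterial and mitochondrial peptides, had 1 read before grafting and 3833 ± 579 normalized counts in grafts, a ratio of 11690 (95% counting interval 2075 to 456700). Serpinb2, a member of the serpin family, had 1 read before and 2667 ± 1052 normalized counts after, a ratio of 8114 (95% counting interval 1451 to 319400). Clec4d, a C-type lectin receptor of myeloid cells, rose by a log2 fold change of 10.90 (SE 0.33).

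The called genes with the largest falls were Thrsp, Cyp2e1, Pnpla3, Adrb3, Cidea, Timp4, Tmem45b, Acsm5, Ces1d and Lep. Thrsp, which promotes lipid synthesis, went from 37193 ± 9902 to 26.9 ± 18.2, a log2 fold change of -10.67 (SE 0.59, adjusted p = 1.39e-05). Adrb3, the beta-3 adrenergic receptor of fat, went from 5265 ± 136 to 8.6 ± 9.1, and Cyp2e1, a cytochrome P450, from 57019 ± 10885 to 102.4 ± 83.5, and without graft replicate 1 these graft means were 3.4 and 67.7. Cidea, a lipid droplet protein, had 877 ± 504 normalized counts before grafting and 1 read in all grafts, a ratio of 2660 (95% counting interval 474.9 to 104600). Acsm5, a medium-chain acyl-CoA synthetase, had 0 reads in every graft and was at least 202-fold lower. Lep, the gene of leptin, went from 9196 ± 1544 to 55.1 ± 81.9, and the graft mean rested on replicate 1, with 149.6 normalized counts against 6.8 and 8.9 in replicates 2 and 3.

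All 20 listed adipocyte markers fell, with a median log2 fold change of -5.75 and a range of -10.67 to -2.38 (camera adjusted p = 1.35e-06, and adjusted p = 0.448 with an estimated correlation). Pparg, the master regulator of adipocyte differentiation, went from 3514 ± 128 to 220.1 ± 141.4 (139.4 without graft replicate 1), a log2 fold change of -4.17 (SE 0.38), and Adipoq had a log2 fold change of -6.68 (SE 0.48). The median of the list was -4.23 in graft replicate 1 and -6.06 and -6.29 in replicates 2 and 3. Of 18 tested genes of fatty acid and triglyceride synthesis, 17 fell, and all 18 when adjusted over the list alone. Lipid synthesis genes had a median log2 fold change of -5.05 (camera adjusted p = 1.2e-06, and adjusted p = 0.437 with an estimated correlation). Fasn, the fatty acid synthase, went from 237915 ± 46836 to 1706 ± 219, and Pck1, which feeds glycerol synthesis in fat, from 25158 ± 11548 to 149.4 ± 197.7, or 35.2 without graft replicate 1. The carbohydrate-responsive transcription factor gene Mlxipl fell by a log2 fold change of -7.31 (SE 1.11), and Dgat1 missed the threshold at -0.99 (adjusted p = 0.0628). Of 11 tested insulin and adrenergic signalling genes, 10 fell, among them Adrb1, Irs1 and Prkar2b, and Adra2a, the alpha-2A receptor, rose from 88.9 ± 26.3 to 367.5 ± 148.7. Insulin and adrenergic genes had a median log2 fold change of -2.86 (camera adjusted p = 0.0016, and adjusted p = 0.437 with an estimated correlation). Of 12 tested brown and beige fat markers, 9 fell, including Cidea, Kcnk3 and Cox8b, and 2 rose (median -3.85, also with the member at 0 set to its bound, camera adjusted p = 0.0333, and adjusted p = 0.437 with an estimated correlation). The 2 that rose were Dio2, which activates thyroid hormone, with a log2 fold change of 3.35 (SE 0.64), and Zic1, a transcription factor of dorsal mesoderm, which had 0 reads before grafting and was at least 61.1-fold higher in grafts. Zic1 had 24.1, 199.8 and 322.5 normalized counts in graft replicates 1, 2 and 3, and the bound was 37.5-fold without graft replicate 3. Tmem26 missed the threshold at 1.19 (adjusted p = 0.0835) and was the third higher gene when adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, was not tested, with mean normalized counts of 14.2 before grafting and 1.0 in grafts.

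**Figure D2:**
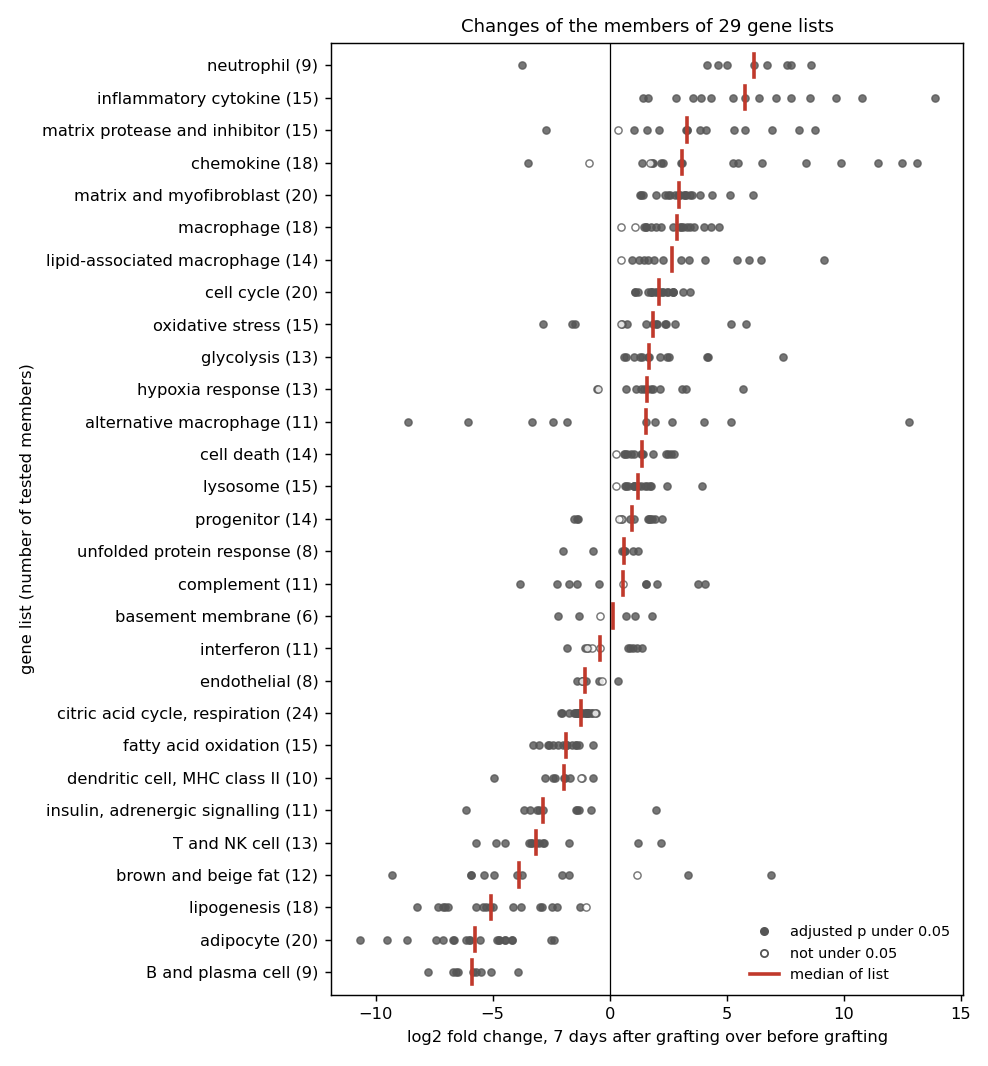
Log2 fold changes of the tested members of 29 gene lists, 7 days after grafting over before grafting (horizontal axis), with 1 point per gene, filled where the adjusted p was under 0.05, and a red bar at each list's median. The medians run from -5.86 for B and plasma cell markers to 6.18 for neutrophil markers, and setting ribosomal protein genes to no change turns the small positive medians of the complement, basement membrane and unfolded protein response lists negative.

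All 15 tested genes of fatty acid oxidation fell (median -1.88, camera adjusted p = 1.67e-05, and adjusted p = 0.448 with an estimated correlation), with Hadh going from 5789 ± 1008 to 606.9 ± 176.5 and Cpt2 falling by a log2 fold change of -2.65. Of 24 genes of the citric acid cycle and respiratory chain, 23 fell, and all 24 when adjusted over the list alone. Citric acid cycle and respiratory chain genes had a median log2 fold change of -1.22 (camera adjusted p = 2.49e-06, and adjusted p = 0.46 with an estimated correlation). The citric acid cycle enzyme genes Idh3a and Sdha fell by log2 fold changes of -2.05 and -1.75, and Cox5b, at -0.61, missed the threshold (adjusted p = 0.17). Among 30 nuclear complex I genes 25 fell, or 28 when adjusted over the list alone, with Ndufa10 at -1.52. Complex I genes had a median log2 fold change of -0.86 (camera adjusted p = 8.42e-05, and adjusted p = 0.505 with an estimated correlation). Ndufa4l2, a hypoxia-induced paralog of a respiratory chain subunit, was the 1 member that rose, from 197.9 ± 6.8 to 930.2 ± 183.7. Of 17 tested mitochondrially encoded genes, 15 fell, or all 17 when adjusted over the list alone, led by mt-Nd2, mt-Ty and mt-Nd4. Mitochondrially encoded genes had a median log2 fold change of -1.59 (camera adjusted p = 0.000193, and adjusted p = 0.448 with an estimated correlation). The mitochondrial chromosome held 4.89 to 6.98% of the listed total before grafting and 1.48 to 1.63% in grafts. Of 38 mitochondrial ribosomal protein genes, 17 fell, including Mrps6, Mrpl49 and Mrps35, and 4 rose, led by Mrpl52 and Mrpl33, against 31 and 7 when adjusted over the list alone. Falls numbered 24 after rescaling by median ratios, 26 with equal listed totals, 31 with upper quartiles equal and 32 with ribosomal protein genes at no change, with 1 to 4 rises. Mitochondrial ribosomal protein genes had a median log2 fold change of -0.46 (camera adjusted p = 0.0131, and adjusted p = 0.592 with an estimated correlation).

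All 13 tested glycolytic enzymes and transporters rose. Glycolytic genes had a median log2 fold change of 1.67 (camera adjusted p = 6.03e-05, and adjusted p = 0.437 with an estimated correlation). Slc16a3, a lactate exporter, went from 40.7 ± 4.9 to 7154 ± 1014, Hk3, a hexokinase of myeloid cells, from 131.7 ± 36.5 to 2411 ± 213, and Slc2a1, the glucose transporter GLUT1, from 323.1 ± 34.6 to 5816 ± 492. Gapdh is listed with mean normalized counts of 97.9 before grafting and 562.5 in grafts, and its value is uncertain because its reads can be shared with many pseudogenes. Of 13 tested targets of the hypoxia response, 11 rose, led by Egln3, Ero1l and Ankrd37 with log2 fold changes of 5.70, 3.25 and 3.08. With ribosomal protein genes at no change, 7 hypoxia targets rose and 2 fell. Hypoxia targets had a median log2 fold change of 1.59 (camera adjusted p = 0.00486, and adjusted p = 0.437 with an estimated correlation). Bnip3, a mitophagy receptor, fell by a log2 fold change of -0.55 (adjusted p = 0.0354), and Vegfa, the angiogenic growth factor, had 5424 ± 831 before and 3923 ± 1275 after, which missed the threshold (adjusted p = 0.246). Of 15 tested antioxidant and iron genes, 11 rose, or 12 when adjusted over the list alone, and 3 fell. Antioxidant and iron genes had a median log2 fold change of 1.84 (camera adjusted p = 0.0226, and adjusted p = 0.448 with an estimated correlation). Hmox1, which degrades heme, went from 924.4 ± 97.5 to 34827 ± 9919, the cystine transporter Slc7a11 from 129.6 ± 54.6 to 7303 ± 2728, and the ferritin heavy chain gene Fth1 from 23182 ± 2137 to 162112 ± 14533. Those that fell were Cat, Sod1 and Gpx4, the genes of catalase, a cytosolic superoxide dismutase and a lipid peroxidase.

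Of 18 macrophage markers, 16 rose, and all 18 when adjusted over the list alone. Macrophage markers had a median log2 fold change of 2.86 (camera adjusted p = 3.65e-06, and adjusted p = 0.437 with an estimated correlation). Adgre1, the F4/80 antigen, went from 851.8 ± 105.8 to 7010 ± 2294, Cd68 from 821.7 ± 106.0 to 5368 ± 330, and the scavenger receptor gene Msr1 from 245.5 ± 23.8 to 6229 ± 683. Itgam and Cd14 rose by log2 fold changes of 4.34 and 4.02, while Mertk (0.49, adjusted p = 0.0815) and Ly6c2 (adjusted p = 0.115) missed the threshold. Of 14 tested genes of lipid-associated macrophages, 13 rose, and all 14 when adjusted over the list alone. Lipid-associated macrophage genes had a median log2 fold change of 2.66 (camera adjusted p = 8.1e-05, and adjusted p = 0.437 with an estimated correlation). Spp1, the gene of osteopontin, went from 42.0 ± 11.7 to 24051 ± 4822, the lipid receptor gene Trem2 from 46.2 ± 17.7 to 1969 ± 373, and Mmp12 and Atp6v0d2 rose by log2 fold changes of 6.48 (SE 0.55) and 5.94 (SE 0.47). The 11 tested genes of alternatively activated and resident macrophages divided into 6 that rose, led by Arg1, Chil3 and Il10, and 5 that fell, led by Retnla and Mgl2 (median 1.57, mean 0.55, camera adjusted p = 0.672). Retnla, a target of interleukin 4, went from 3617 ± 229 to 10.4 ± 9.5 (5.0 without graft replicate 2), and 3 of the 5 falls were called without replicate 2 before grafting. Chil3 differed widely between grafts, with an SD of 1961 around a mean of 1880, which was 794.9 without graft replicate 1.

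All 15 tested proinflammatory cytokine and inflammasome genes rose. Cytokine and inflammasome genes had a median log2 fold change of 5.77 (camera adjusted p = 4.1e-06, and adjusted p = 0.437 with an estimated correlation). Tnf went from 65.8 ± 14.9 to 1329 ± 224, Il6 from 2.0 ± 1.7 to 575.3 ± 262.1, and Il1rn, the interleukin 1 receptor antagonist, from 18.8 ± 6.7 to 16179 ± 5884. Of 18 tested chemokines, 15 rose, or 16 when adjusted over the list alone, and the monocyte chemokine Ccl2 went from 42.4 ± 5.4 to 2014 ± 668 (median 3.08, also with the member at 0 set to its bound, camera adjusted p = 5.12e-05, and adjusted p = 0.437 with an estimated correlation). Ccl22 was the 1 chemokine that fell, by a log2 fold change of -3.50 (SE 0.85, adjusted p = 0.0269). Of 9 tested neutrophil markers, 8 rose. Neutrophil markers had a median log2 fold change of 6.18 (camera adjusted p = 0.0038, and adjusted p = 0.448 with an estimated correlation). The calprotectin genes S100a8 and S100a9 went from 70.6 ± 38.8 to 14712 ± 4843 and from 120.8 ± 54.1 to 23252 ± 10252, and Lcn2, an iron-sequestering protein, from 48.6 ± 23.8 to 18261 ± 3371. Elane, the neutrophil elastase of bone marrow precursors, fell from 34.1 ± 3.2 to 2.3 ± 2.5, or 1.0 without graft replicate 3. The 11 tested complement genes divided into 5 that rose, with the receptor genes C3ar1 and C5ar1 and the properdin gene Cfp in the lead, and 5 that fell, with C7 and C6 in the lead, against 6 and 5 when adjusted over the list alone. Complement genes had a median log2 fold change of 0.58, or -0.18 with ribosomal protein genes at no change (camera adjusted p = 0.623), and 3 of the falls were called without replicate 1 or replicate 2 before grafting. Of 11 tested interferon-stimulated genes, 5 rose, led by Isg15, Oas1a and Zbp1, and 3 fell, led by Ifit3 and Usp18, with 6 falls when adjusted over the list alone (median -0.41, camera adjusted p = 0.715). Under the other scalings falls outnumbered rises: 2 rose and 5 fell after rescaling by median ratios or with equal listed totals, 2 and 6 with upper quartiles equal, and 0 and 6 with ribosomal protein genes at no change. Rises numbered 1 without replicate 2 or replicate 3 before grafting, 3 without graft replicate 2 and 2 without graft replicate 3, and falls numbered 5 without graft replicate 2.

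All 9 tested B and plasma cell markers fell. B and plasma cell markers had a median log2 fold change of -5.86 (camera adjusted p = 0.000376, and adjusted p = 0.448 with an estimated correlation). Fcer2a, the low-affinity IgE receptor, went from 1307 ± 423 to 6.3 ± 4.6, the complement receptor gene Cr2 from 1222 ± 493 to 11.8 ± 4.9, and the IgM receptor gene Fcmr from a mean of 1033 to 13 normalized counts, or 5.0 without graft replicate 2. Of 37 tested immunoglobulin variable segments, 26 fell, or 34 when adjusted over the list alone, among them Ighv7-3, Iglv2 and Igkv3-12 (median -3.54, or -3.53 with members at 0 set to their bounds, camera adjusted p = 3.2e-05, and adjusted p = 0.448 with an estimated correlation). The count was 14 without replicate 1 and 11 without replicate 3 before grafting, and single segments are uncertain because near-identical segments share reads. Of 13 tested T and NK cell markers, 11 fell and 2 rose. The NK cell receptor genes Klrb1c and Ncr1 and the perforin gene Prf1 of this list were outside the table and not analysed here. T and NK cell markers had a median log2 fold change of -3.14 (camera adjusted p = 0.0105, and adjusted p = 0.517 with an estimated correlation). The T cell co-receptor genes Cd8a and Cd8b1 fell by log2 fold changes of -4.84 and -5.71 and Cd3e by -4.47, and the granzyme genes Gzmb and Gzma rose by 2.18 and 1.21, with Gzma not called with upper quartiles equal or ribosomal protein genes at no change. Of 10 tested dendritic cell and MHC class II genes, 8 fell, or all 10 when adjusted over the list alone, including Xcr1, Ccr7 and Cd209a (median -1.94, camera adjusted p = 0.00878, and adjusted p = 0.448 with an estimated correlation), and 4 fell without replicate 1 or replicate 3 before grafting. Cd74, the invariant chain, had 25113 ± 4331 before and 11710 ± 5683 after (adjusted p = 0.0609). The MHC class II genes H2-Aa, H2-Ab1, H2-Eb1 and H2-DMb1 of this list were outside the table and not analysed here. Among 4 tested lymph node markers 3 fell, namely Glycam1, Cxcr5 and Ltb, and the 1 other, Ccl21a, missed the threshold (-4.20, SE 1.41, adjusted p = 0.105), with all 4 called lower when adjusted over the list alone. Glycam1, a ligand made by the high endothelial venules of lymph nodes, went from 852.2 ± 280.1 to 22.3 ± 11.8.

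**Figure D3:**
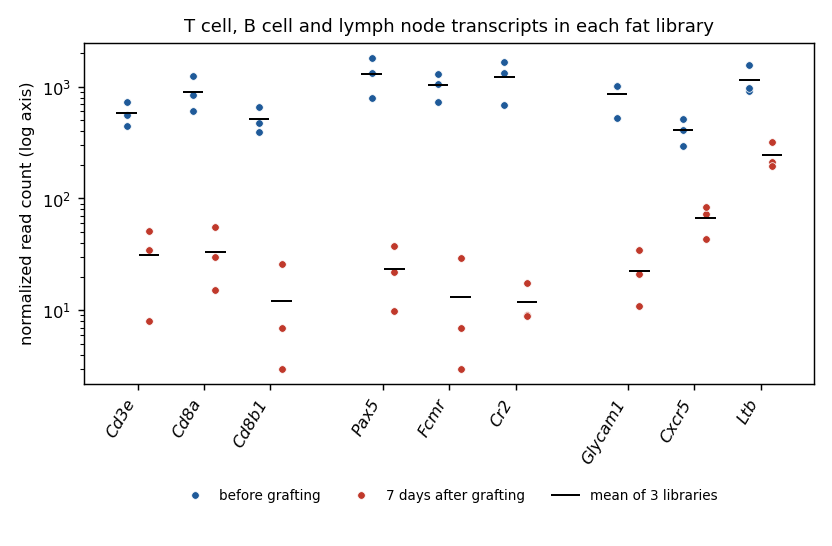
Normalized read counts (vertical log axis) of T cell (Cd3e, Cd8a, Cd8b1), B cell (Pax5, Fcmr, Cr2) and lymph node (Glycam1, Cxcr5, Ltb) transcripts in each of the 6 fat libraries, blue before grafting and red 7 days after grafting, with a black bar at the mean of 3 libraries. All 9 transcripts lie lower in all 3 grafts than in the 3 libraries before grafting.

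All 20 fibrillar collagen, matrix and myofibroblast genes rose. Matrix and myofibroblast genes had a median log2 fold change of 2.98 (camera adjusted p = 1.35e-06, and adjusted p = 0.448 with an estimated correlation). Col1a1 went from 24562 ± 4477 to 356037 ± 69966, Col3a1 from 72850 ± 8960 to 448038 ± 138085, and the matrix proteins Col12a1 and tenascin C (Tnc) rose by log2 fold changes of 6.14 and 5.15. Lox, which crosslinks collagen, went from 1182 ± 128 to 24267 ± 2401. Over 29 tested collagens of any type, 20 rose, with Col24a1, Col12a1 and Col8a2 in the lead, and 6 fell, led by Col6a6 and Col4a4, with 9 falls when adjusted over the list alone. Collagens had a median log2 fold change of 1.49 (camera adjusted p = 0.0159, and adjusted p = 0.462 with an estimated correlation). Of 15 matrix protease and inhibitor genes, 13 rose, or 14 when adjusted over the list alone. Protease and inhibitor genes had a median log2 fold change of 3.30 (camera adjusted p = 0.000126, and adjusted p = 0.448 with an estimated correlation). Timp1, a metalloproteinase inhibitor, went from 16.9 ± 2.0 to 8045 ± 1758. Mmp13, a collagenase, went from 3.7 ± 3.0 (2.0 without replicate 2 before grafting) to 1891 ± 2060, with graft values between 292.3 and 4215.7 and a mean of 728.3 without graft replicate 2, and Timp3 fell by a log2 fold change of -2.73. Of 14 tested mesenchymal progenitor genes, 8 rose, including Clec11a, F3 and Icam1, or 11 when adjusted over the list alone, and Dpp4, Cd55 and Zfp423 fell. Progenitor genes had a median log2 fold change of 0.95 (camera adjusted p = 0.0786), or 0.19 with 6 rises and 3 falls with ribosomal protein genes at no change. Pdgfra, a receptor of fibroblasts and progenitors, went from 1742 ± 233 to 5602 ± 1441. The 6 tested basement membrane genes divided into 3 that rose (Col18a1, Nid2, Lamb1) and 2 that fell (Lama2, Lamb2), with a median of 0.14, a mean of -0.06 and a camera adjusted p of 0.961, and the median was negative with upper quartiles equal (-0.05) or ribosomal protein genes at no change (-0.62, with 1 rise).

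Of 8 tested endothelial markers, 5 fell, or 6 when adjusted over the list alone, among them the growth factor receptor genes Kdr and Tek and the guidance receptor gene Robo4, with log2 fold changes of -1.40, -1.14 and -1.17. All 8 fell with ribosomal protein genes at no change. Endothelial markers had a median log2 fold change of -1.07 (camera adjusted p = 0.0603). Plvap, of fenestrated endothelium, was called higher at 0.38, was not called under the 3 other rescalings, and was -0.38 with ribosomal protein genes at no change. Acta2, smooth muscle actin, rose from 1244 ± 44 to 3870 ± 583, while the other 4 tested smooth muscle and pericyte genes, Cspg4, Myh11, Rgs5 and Lmod1, fell. Smooth muscle and pericyte genes had a median log2 fold change of -1.24 (camera adjusted p = 0.169). All 6 tested Schwann cell genes fell, including Cdh19 and S100b, and 4 to 5 were called lower when 1 library was left out. Schwann cell genes had a median log2 fold change of -1.41 (camera adjusted p = 0.0326, and adjusted p = 0.448 with an estimated correlation). Of 5 tested lymphatic endothelial genes, Prox1, Reln and Mmrn1 fell, 4 fell when adjusted over the list alone, and Pdpn, which fibroblasts and macrophages also express, rose from 156.5 ± 23.5 to 4560 ± 943 (camera adjusted p = 0.4). Their median was -3.86, while fry gave the direction as up (adjusted p = 0.355).

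All 20 proliferation genes rose (median 2.12, camera adjusted p = 1.41e-05, and adjusted p = 0.448 with an estimated correlation), with Mki67 going from 857.6 ± 279.0 to 2779 ± 333 and the mitotic genes Ccnb1, Cdk1 and Ccnb2 rising by log2 fold changes of 3.43, 3.15 and 2.72. Of 14 cell death genes, 13 rose, and all 14 when adjusted over the list alone (median 1.38, camera adjusted p = 0.000302, and adjusted p = 0.437 with an estimated correlation), including the BCL2 family genes Bcl2a1b and Bcl2l11 and the inflammatory caspase gene Casp4, although 7 rose and 1 fell with ribosomal protein genes at no change. Of 15 tested lysosomal genes, 14 rose, and all 15 when adjusted over the list alone, led by Gla, Ctsl and Ctsz, although 8 rose with ribosomal protein genes at no change. Lysosomal genes had a median log2 fold change of 1.21 (camera adjusted p = 8.1e-05, and adjusted p = 0.437 with an estimated correlation). Of 16 tested vacuolar ATPase genes, 11 rose, or 14 when adjusted over the list alone, including Atp6v1a and Atp6v0c, and Atp6v0e2 fell, with 2 falls when adjusted over the list alone. Without a pseudogene that the name pattern caught, 11 of 15 rose. Vacuolar ATPase genes had a median log2 fold change of 0.83, or 0.07 with ribosomal protein genes at no change, where 5 rose and 4 fell (camera adjusted p = 0.00709, and adjusted p = 0.448 with an estimated correlation). Of 26 proteasome genes, 17 rose, led by Psmd10, Psma5 and Psmb5, but 9 rose after rescaling by median ratios or with equal listed totals, 8 with upper quartiles equal, and 0 rose and 10 fell with ribosomal protein genes at no change, and the count of rises was 10 without replicate 1 or replicate 3 before grafting or without graft replicate 1 or 2. Proteasome genes had a median log2 fold change of 0.42, or -0.34 with ribosomal protein genes at no change (camera adjusted p = 0.00169, and adjusted p = 0.462 with an estimated correlation). Adjusted over the list alone, 25 proteasome genes rose and 1 fell, and without Psmc3ip, which is not a proteasome subunit, 17 of 25 rose over all genes. Of 8 tested genes of the unfolded protein response, 6 rose, led by Atf4, Sdf2l1 and Hspa5, and Asns and Herpud1 fell (median 0.60, camera adjusted p = 0.311), and with ribosomal protein genes at no change the median was -0.16 and 1 rose. Of 89 tested genes with a ribosomal protein name, 76 rose, or 85 when adjusted over the list alone, and Rps6ka5 and Rps6kb1 fell, or 4 genes when adjusted over the list alone (median 0.76, camera adjusted p = 2.45e-07, and adjusted p = 0.448 with an estimated correlation), a rise that is 0 by construction under the ribosomal scaling. These 2, and Rps6ka2 among the largest rises, are kinases of ribosomal protein S6 and not ribosomal proteins, and without the 7 kinases 72 of 82 rose and 0 fell. Of 7 tested housekeeping genes 5 rose, including Pgk1, Gusb and Actb, and Sdha fell, or 2 when adjusted over the list alone or without graft replicate 2 (median 0.82, or 0.06 with 2 rises under the ribosomal scaling, camera adjusted p = 0.206).

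All 46 lists with at least 5 tested members were tested together with camera, which called 32 of them, 18 up and 14 down, with the preset correlation and 0 with an estimated correlation. Counts adjusted over the list alone equalled those over all genes where no second count is given. In that adjustment, untested members of the list counted at the highest possible p. The values of Cd74, Ccl21a, Cox5b, Dgat1, Gapdh, Gpx4, Lmod1, Ly6c2, Mertk, Pax5, Tmem26 and Zfp423 had been seen before these genes were chosen for mention. For each of the 210 called genes under the naming rule, the 3 grafts lay on 1 side of the 3 libraries before grafting. The same held for 97.6% of all tested genes, in a table selected for difference, and the rule itself required it of the largest changes. When at least 1 library was left out, 27 of the 210 lost their call and 0 reversed. Without replicate 1 before grafting, those that lost it were C6, Ccl22, Ccr7, Cd209a, Cdh1, Dpp4, Gzma, Hspa5, Ighv7-3, Iglv2, Kdm5d, Krt20, Mmrn1, Mrgprb1, Plvap, Treml1, Usp18 and mt-Ty (adjusted p from 0.0512 to 0.16). Without replicate 2 before grafting, they were Bnip3, C6, Ccl22, Ccr7, Cd209a, Cdh1, Cox8b, Gzma, Hist1h1e, Hist3h2ba, Isg15, Kdm5d, Krt20, Krt7, Mmrn1, Mrgprb1 and Zbp1 (adjusted p from 0.0551 to 0.208). Without replicate 3 before grafting, they were Bnip3, C6, Ccl22, Ccr7, Cd209a, Cdh1, Ciart, Gzma, Hist3h2ba, Hspa5, Ighv7-3, Iglv2, Isg15, Kdm5d, Krt20, Krt7, Mmrn1, Mrgprb1, Plvap, Rpl36al, Treml1, Zbp1 and mt-Ty (adjusted p from 0.0512 to 0.179). Without graft replicate 1, they were Ccl22, Ccr7, Cd209a, Hspa5, Kdm5d, Krt20, Krt7, Plvap and Treml1 (adjusted p from 0.0504 to 0.105). Without graft replicate 2, they were Bnip3, Cdh1, Gzma, Hspa5, Kdm5d, Krt20, Krt7, Mrgprb1, Plvap, Treml1 and Zbp1 (adjusted p from 0.0522 to 0.143), and without graft replicate 3, Bnip3, Cdh1, Ciart, Gzma, Krt7, Plvap, Treml1, Usp18, Zbp1 and mt-Ty (adjusted p from 0.0505 to 0.138). After rescaling by median ratios, the named genes that lost their call were Cdh1, Krt7, Plvap and Zbp1 (adjusted p from 0.0576 to 0.1182). Equal listed totals took it from these 4 and Mmrn1, and equal upper quartiles from these 4, Gzma and Hspa5. With ribosomal protein genes at no change, 21 lost it, namely Actb, Cdh1, Ciart, Gzma, Hist1h4i, Hspa5, Isg15, Krt20, Krt7, Lamb1, Mrpl33, Nid2, Oas1a, Psma5, Psmb5, Psmd10, Rpl36al, Rpl39l, Sdf2l1, Treml1 and Zbp1. Of these, Hspa5 and Lamb1 also changed direction, and under that scaling Plvap (-0.38, adjusted p = 0.0232) and Vegfa (-1.27, adjusted p = 0.00337) were called lower.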

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

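The rescalings, pseudocounts, precision weights, unmoderated variances, adjustment over listed genes, treat and the shorter name families were tests chosen after the data were seen. The 8730 calls, 4479 higher and 4251 lower, became 5804 (2782 higher) with an absolute log2 fold change of at least 1, and 3019 (1495 higher and 1524 lower) with treat against a log2 fold change of 1, because both ask for a larger change. With ribosomal protein genes at no change, 1947 were higher, because that scaling lowers every fold change. Of 6336 calls it shared with the 8730, 6198 kept their direction. Among the named genes, Hspa5 (-0.12, adjusted p = 1), Lamb1 (-0.064, adjusted p = 1) and Plvap (-0.38, adjusted p = 0.0232) reversed. Camera called 0 lists with an estimated correlation, which allows for correlated members but leaves the test few degrees of freedom with 6 libraries. The 0 therefore cannot tell correlated members from low power. Leaving out 1 library gave 7080 to 8144 calls, 3752 to 4130 higher and 3326 to 4014 lower. The other 13 settings gave 6422 (without moderation) to 10769 (adjusted over listed genes) calls. The replicate term gave 7556, of which 7490 were shared with the 8730. Of 4634 values of named genes over all settings, 4336 kept direction and side of the threshold, 285 lost and 4 gained the call, 6 moved and 3 reversed, 2 of which also lost the call. The ratio of means gave no value for genes with 0 reads in a group. Of 945 list counts of at least 5, 98 moved by over 1.5 times, 92 of them down. Count models, voom and glmTreat were not run, so their calls are not known; the per-sample tables hold the same values. Selection of the table, unknown full depth and 3 libraries per group limit all of these.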

Other observations

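The Hox genes, En1, Six4, Irx1, Irx5, H19 and the tests on lymphocyte genes were chosen after the result was seen. Of 13 tested Hox genes, 12 were called lower in grafts and 0 higher, with a median log2 fold change of -1.76, in a table that had been selected for difference, and Hoxb8 missed the threshold (-0.51, adjusted p = 0.217). Hoxa9 went from 316.2 ± 82.4 to 49.6 ± 27.4 normalized counts, and Hoxc10 from 252.8 ± 29.7 to 53.2 ± 34.6, or 34.2 without graft replicate 1. En1 rose from 47.4 ± 3.6 to 385.8 ± 191.7, Six4 from 5.0 ± 3.1 to 156.4 ± 55.9, and Irx1 and Irx5 by log2 fold changes of 1.99 and 2.20. Wt1, a mesothelial marker, had 0 reads before grafting and was at least 26.4-fold higher in grafts, although reads of its antisense neighbour may be included, since strand use is not given. Lrrn4 and Gpm6a, the other 2 of 3 tested mesothelial markers, fell (median -2.46, also with Wt1 at its bound). With no filter on low values, 3 more mesothelial markers were tested, 4 of 6 rose and 2 fell, and the median was above 0.

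All 10 immediate early genes rose, led by Fos, Junb and Fosb (median 3.46, camera adjusted p = 0.000223, and adjusted p = 0.448 with an estimated correlation). Immediate early genes were listed as a check because they move with the handling of tissue, and clock genes because they move with the hour of collection. Whether handling or hour differed between the groups was not tested. Of 9 tested clock genes, Per3, Per2, Dbp, Tef and Nr1d2 fell and Npas2, Ciart, Arntl and Nr1d1 rose (camera adjusted p = 0.292), with 2 rises without replicate 1 or 3 before grafting or graft replicate 2 or 3. Clock gene rises numbered 3 after rescaling by median ratios, 4 with equal listed totals, 2 with upper quartiles equal and 1 with ribosomal protein genes at no change, with 5 falls in each. Of 4 tested platelet genes, Ppbp, Pf4 and Treml1 rose and Itga2b fell. Of 5 tested mast cell genes, Mrgprb1 fell, 4 fell when adjusted over the list alone (camera adjusted p = 0.169), and without 1 library between 0 and 5 fell, 5 of them without graft replicate 3, 3 without graft replicate 1 and 0 otherwise, and 4 fell with ribosomal protein genes at no change. Of 13 tested genes with a histone name, 7 fell, led by Hist1h4h, Hist3h2ba and Hist1h1e, and 5 rose, led by H19 and Hist1h4i (camera adjusted p = 0.604), with 4 falls without replicate 2 before grafting and 1 rise with ribosomal protein genes at no change. H19, a long noncoding RNA, and H13, a peptidase, are not histones, and without them 3 rose and 7 fell. Krt20, Krt80 and Krt7 rose and Krt222 fell among 5 tested keratins, with 2 falls when adjusted over the list alone (camera adjusted p = 0.708), with 1 rise without replicate 2 or 3 before grafting or graft replicate 1 or 2. Keratin rises numbered 2 under 3 of the other scalings, and 1 with 2 falls with ribosomal protein genes at no change. Both tested major urinary protein genes fell, with ratios of 67.4 for Mup3 (95% counting interval 11.7 to 2703) and 50.3 for Mup11 (95% counting interval 8.63 to 2027), which share reads with near-identical paralogs. Kdm5d, a Y-linked gene, fell by a log2 fold change of -0.66, and without any 1 library except graft replicate 3 it was not called, while Uty was -0.39 (adjusted p = 0.1), and both fell when adjusted over the list alone. Cdh1 was the 1 tested epithelial marker, at 1.07, and was called over all genes. It was not called when adjusted over the list alone, because all 12 list members counted, the untested ones at the highest possible p. Nor was it called under any of the 4 other scalings, at 0.96, 0.95, 0.89 and 0.32. The skeletal muscle, male tract and red cell lists had 0 members in the table and were not analysed here.

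The 10 splits of the 6 libraries were too few for a share under 0.05: 1 of them, the real one, called 8730 genes with limma, and the highest of the other splits called 0, with 0 to 12 genes at an unadjusted p under 0.05.

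Adipocyte markers fell by different amounts. The SD of their log2 fold changes was 4.23 times the mean SE, which argues against all markers falling by 1 common factor. It cannot tell whether loss of adipocytes was the whole cause, because any marker also expressed by other cells of the grafts would fall by less. Under every other scaling tried, the median was -5.86 or lower. Those scalings moved the median of all tested genes only from 0.28 to between 0.17 and -0.48, and rest on genes selected for difference. They could not have undone a fall of this size, so they cannot decide on the authors' scaling. A loss of adipocytes together with lower expression in those that remain may account for the pattern and was not tested.

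Of 18 macrophage markers 16 rose, and of 8 endothelial markers 5 fell and 1 rose. Their medians differed by 3.92 (exact permutation p = 0.000106, two-sided, across genes, which are not independent replicates), which argues against a lower share of adipocytes raising all other cell types alike. The comparison covers only the 8 of 14 endothelial markers that were in the table, which had been selected for difference. The lowest macrophage median under another scaling was 2.09. The scalings tried were too near each other to undo a rise of this size, so they cannot decide on the authors' scaling. Blood left in the grafts cannot be told apart, because 0 red cell transcripts were tested. Infiltration of macrophages after grafting remains a hypothesis, and the median was between 2.68 and 2.85 in all 3 grafts.

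All 9 tested B and plasma cell markers fell and 16 of 18 macrophage markers rose. Their medians lay -8.71 apart, which argues against a loss of all leukocytes alike. The comparison was chosen after both directions were seen. Its exact permutation p (p = 0.000106, two-sided, across genes, which are not independent replicates) therefore adds no support. The highest B and plasma cell median under another scaling was -5.97. Again the scalings tried were too near each other to undo a fall of this size, so they cannot decide on the authors' scaling. Lymph node tissue in the fat before grafting cannot be told apart from a loss of the fat's own lymphocytes. The 2 of 4 named high endothelial venule genes that were in the table, Glycam1 and Chst4, were both called lower. They were listed for a difference and named after the fall of Glycam1 was seen, so their calls add no support. In replicates 1, 2 and 3 before grafting, Glycam1 had 1007.7, 528.8 and 1020.0 normalized counts and Chst4 had 80.9, 47.6 and 74.8. Both transcripts were therefore present in every library before grafting. Chst4, a sulfotransferase, went from 67.7 ± 17.7 to 1.3 ± 1.5 normalized counts (0.5 without graft replicate 1), and Cd8a, Cr2 and other lymphocyte genes are also expressed by lymphocytes of fat itself. A loss of resident lymphocytes after grafting stays open.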
